A study of Arabidopsis thaliana with 9 samples.

How the data were processed

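Whole Arabidopsis thaliana seedlings of accession Col-0 were grown on agar and then in shaken liquid culture, treated with 0.1 mM silver nitrate and sampled at 0, 48 and 72 h. The groups and replicate numbers came from the labels, which describe 3 independent experiments with different plants per time. RNA of each sample was labelled with 1 dye (Cy3) and hybridised to an Agilent array, so there were 9 arrays on 4 slides. Replicate 1 of every time was on slide 1, replicate 2 on slide 2, replicate 3 of 0 h and 48 h on slide 3 and replicate 3 of 72 h on slide 4. Slide positions were read from the deposited scanner files, and slide was used as a batch.

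For each array the authors deposited a scanner file from Agilent Feature Extraction 9.5.3.1, whose processed signal is an intensity, background subtracted and spatially detrended but not scaled between arrays. The deposited scanner files also hold the median signal and background intensity of each spot and other columns, which mark whether a spot is well above background, saturated or an outlier. The series also has a deposited value table, whose values are a ratio on a linear scale. The authors did not state its scaling factor per array or its reference level per probe. For 22644 probes above background on all arrays, differences between arrays in the log2 of this table equalled those of the processed signal up to 1 constant per array, so its scale and direction were known. For 37.3% of probes it has an array at exactly 1, and the medians of the arrays were 0.901 to 1.11. It was used only as an alternative.

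Each file held 39102 spots, of which 37685 were not controls. Control spots were left out, 80 outlier spots over all arrays were dropped, and no spot was saturated. Spots of a probe were averaged, which concerned 23 probes printed 10 times. Replicate spots had a median coefficient of variation of 3.2% to 4.1%. Values were log2 of the processed signal minus the 75th percentile of the array. A probe was kept if it was well above background on all 3 arrays of at least 1 time. Genes were identified by locus, known for 26236 of 37478 probes (25665 loci, 541 with several probes), and the probe with the highest mean over the 9 arrays stood for the locus. This left 21042 genes. The locus of 26019 probes was in the reference gene table used for symbols, and 10461 probes had a symbol. Probes designed on genome positions (8812) or on expressed sequence tags and other accessions (2430) have no locus and were not part of the gene comparisons. No genome build is named for the probes, so positions are not given.

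Genes were tested with limma 3.58.1 in R 4.3.3, by a model with 1 mean per time fitted to all 9 arrays and moderated variances (6 residual and 2.54 prior degrees of freedom, median standard error 0.194). Tests were two-sided with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Comparisons were 48 h with 0 h, 72 h with 0 h, 72 h with 48 h, an F test over the 3 times, and the overlap of calls at 48 h and 72 h. Where a probe was well above background on no array of 1 of the times compared, its change is given as a lower bound. With 1 or 2 such arrays at a time the fitted change is given, with their number. Choices, lists and alternatives were fixed before the data were examined, except where stated.

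The lists held 362 genes in 27 groups, chosen for silver, metals, defence and stress, and for organs and cell types of a seedling. They were tested with limma's fry, adjusted over the 27 lists. fry tests whether the genes of a set move on balance one way, and does not compare them with other genes. camera with a preset correlation of 0.01 and with an estimated correlation were alternatives. All 31 fry calls at 48 h and 72 h were lost with the estimated correlation, for which the smallest adjusted p was 0.206 at 48 h and 0.265 at 72 h. Members were identified by the locus written beside the symbol. The lookup by symbol that had been planned sent 5 members to unrelated genes, so it was replaced before expression values were seen, and its loci were kept as an added alternative. Families of at least 10 genes whose symbols open with the same letters (139 families) were tested among rises and falls with a one-sided Fisher's exact test against 9232 tested genes with a symbol, adjusted over all families and both directions.

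Genes were named by a rule. For 48 h and 72 h against 0 h it took called genes with a symbol that moved the same way in all 3 same-numbered pairs of arrays: the 8 largest rises and 8 largest falls of genes above background on all arrays of both times, and the 4 largest lower bounds each way. For each list it took up to 3 called members with the largest change at 72 h, or the member with the smallest p where none was called, and reference genes could always be named. For 72 h against 48 h the rule gave no gene. Genes outside the rule are said to have been named after their values were seen.

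Whether replicate numbers pair arrays was checked by correlating deviations from the group mean, across genes. For 48 h and 0 h the same-numbered arrays gave 0.255, 0.317 and 0.401, each the best match. All 3 pairs were on shared slides, so pairing by experiment cannot be told apart from a shared slide. With replicate as a block, 6744 genes were called at 48 h. The planned model has no block, and blocks for replicate and for slide were alternatives. Lists are given with the slide as a block and within each slide. Slides 1, 2 and 3 hold arrays of 0 h and 48 h, and slides 1 and 2 hold arrays of 0 h and 72 h. With the slide as a fixed block, replicate 3 of 72 h, alone on its slide, adds nothing to the shifts at 72 h. Those shifts then rest on replicates 1 and 2 of 72 h.

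The tests of genes and lists were tried on simulated values for 21042 genes, with changes at 48 h only. Scaling, the filter, the choice of probes and the family test were not part of this. Of 100 genes changed by 1 log2 unit, 44% were called, and of 100 changed by 2 log2 units, 80%, with 0 in the wrong direction and 10 unchanged genes called. Of 100 random lists, 0 were called. Genes were simulated as independent and few were changed. The simulation therefore does not cover lists whose genes move together, or data in which many genes change. Alternatives were normexp background correction (offset 50, on the median spot and background signals because mean signals were not in the files), quantile normalization, median scaling, the deposited value table, no filter on dim probes, a filter requiring all 9 arrays, probe means, replicate and slide blocks (with a random slide effect through statmod 1.5.0), leaving out each array in turn, fitting only the 6 arrays compared, a limit of 2-fold, an intensity trend with robust variances, and probes in place of genes. Leaving out slides 3 and 4 together was added after seeing the data. The number of arrays limits the precision of all values.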

Results

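Gene expression was measured in whole seedlings of Arabidopsis thaliana (accession Col-0) kept in shaken liquid culture with 0.1 mM silver nitrate, a salt that releases toxic silver ions. Plants were sampled at 0 h and after 48 h and 72 h. Each time was represented by 3 arrays, from separate experiments with different plants, so 9 arrays with 1 fluorescent dye were compared. Each array held 39102 spots, and between 65.4% and 68.3% of spots were well above background. The 75th percentile of the signal lay between 1612 and 3732 intensity units, with the lowest values on replicate 3 of 0 h (1612) and of 48 h (1997). Those 2 arrays shared slide 3, and replicate 3 of 72 h stood alone on slide 4. Within a time, arrays correlated across genes at 0.963 to 0.984 (0 h), 0.983 to 0.988 (48 h) and 0.981 to 0.991 (72 h), where genes are not independent replicates. The comparisons address how the transcriptome of seedlings changes during exposure to silver. The 0 h plants were the only reference, so effects of silver and of 48 or 72 further hours in culture cannot be told apart, and the number of arrays limits the precision. Changes below are log2 differences from 0 h ± standard error, from 3 arrays per time, and all list shifts are log2 means over measured genes. Shifts at 72 h with the slide as a block rest on 2 arrays of 72 h, without the one on slide 4.

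After 48 h, transcripts of iron regulation and of indole defence were among the largest rises of measured genes. The iron-deficiency transcription factor gene bHLH38 (AT3G56970) rose 221-fold (7.79 ± 0.50, adjusted p = 4.61e-05) and its relative bHLH39 (AT3G56980) rose 97.9-fold (6.61 ± 0.41). The cytochrome P450 genes CYP82C2 (AT4G31970, 72.6-fold, 6.18 ± 0.71) and CYP71A12 (AT2G30750, 56.0-fold, 5.81 ± 0.43), whose enzymes make tryptophan-derived defence compounds, rose with them. NEET (AT5G51720), which encodes an iron-sulfur protein, fell 64.6-fold (-6.01 ± 0.42), and CA1 (AT3G01500), which encodes a chloroplast carbonic anhydrase, fell 32.1-fold (-5.0 ± 0.37). Several cold- and stress-responsive transcription factor genes, some of which also respond within minutes to touch, were lower than at 0 h: CBF4 (AT5G51990, -5.79 ± 0.40), CBF2 (AT4G25470, -4.47 ± 0.22) and RRTF1 (AT4G34410, -5.76 ± 0.63).

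Other large rises included DIN2 (AT3G60140, 5.75 ± 0.77), a beta-glucosidase gene, and ABCG40 (AT1G15520, 5.64 ± 0.90), which encodes an ABC transporter. The serine carboxypeptidase-like gene scpl30 (AT4G15100, 5.53 ± 0.68) and ARD3 (AT2G26400, 5.14 ± 0.53), of the acireductone dioxygenase family of methionine salvage, also rose. Among the falls were the aldolase gene FBA5 (AT4G26530, -5.99 ± 0.62) and the cell wall gene XTH14 (AT4G25820, -5.09 ± 0.52). RHS19 (AT5G67400), a root hair gene, fell as well (-4.47 ± 1.13, adjusted p = 0.0180), a call that ended without 48 h replicate 3 (adjusted p = 0.0574). Some genes were above background on no array of 1 time, so only a lower bound on their change can be given. The seed storage albumin gene SESA5 (AT5G54740) was at least 87.9-fold higher, the sucrose transporter gene SUC7 (AT1G66570) at least 44.9-fold higher and the receptor-like kinase gene CRK37 (AT4G04500) at least 15.1-fold higher. AHG1 (AT5G51760), a protein phosphatase gene of abscisic acid signalling, was at least 19.5-fold higher, a call that ended with normexp background correction (adjusted p = 0.0948). The root hair genes RHS18 (AT5G22410) and MRH6 (AT2G03720) were at least 33.3-fold and at least 26.0-fold lower, ddf2 (AT1G63030), a relative of the CBF genes, at least 32.8-fold lower, and CYP718 (AT2G42850) at least 23.7-fold lower.

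In all, 6298 of 21042 genes tested (29.9%) passed an adjusted p of 0.05 at 48 h, 2968 higher and 3330 lower than at 0 h. Of these, 1683 rose and 1911 fell at least 2-fold. The share of calls that were higher was 47.1%, and under the 4 other scalings 38.5% (median scaling), 39.4% (normexp), 49.5% (quantile normalization) and 59.6% (deposited value table, where the median of all genes moved by 0.151). With slides 3 and 4 left out, an alternative chosen after seeing the data, 3024 genes passed. Of genes named here for 48 h, the calls of RHS19, BGLU28, SULTR1;1, CYP81F1, CYP81F2, 4CL1, IRX1, MUTE and ACT2 then ended (adjusted p = 0.0519 to 0.164).

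Metal-related lists moved unevenly at 48 h. Of 11 measured iron deficiency genes, 8 rose, 1 fell and 2 did not pass the test (8 and 1 when adjusted over the list alone). BHLH100 (AT2G41240, 9.08 ± 0.88, above background on 2 of 3 arrays at 0 h) rose with bHLH38 and bHLH39, while the iron store gene FER1, named after its values were seen, fell (-3.14 ± 0.36). The mean shift was 3.19 (fry adjusted p = 0.000131; adjusted p = 0.206 with an estimated correlation), between 3.02 and 3.36 within single slides, and with the slide as a block the shift was 3.19 (adjusted p = 0.000234). Among 14 sulfur assimilation genes, 11 rose, 1 fell and 2 did not pass the test (11 and 1 when adjusted over the list alone). They included BGLU28 (AT2G44460, 4.66 ± 0.84), a glucosidase gene of sulfur starvation, and GGCT2;1 (AT5G26220, 3.61 ± 0.47), of glutathione breakdown, whereas the sulfate transporter gene SULTR1;1 (AT4G08620) fell (-2.37 ± 0.51, above background on 1 of 3 arrays at 48 h). Their mean shift of 1.94 had a fry adjusted p of 0.000615, and an adjusted p of 0.206 with an estimated correlation. Slide by slide it lay between 1.59 and 2.35, and with the slide as a block the shift was 1.94 (adjusted p = 0.0105). Copper homeostasis genes split: of 14, 5 rose, 5 fell and 4 did not pass the test (6 and 6 when adjusted over the list alone). The transporter gene ZIP2 (AT5G59520, -1.80 ± 0.29) and the iron superoxide dismutase gene FSD1 (AT4G25100, -2.22 ± 0.32) fell and the plantacyanin gene ARPN (AT2G02850, 1.92 ± 0.31) rose. The copper list as a whole was not called (fry adjusted p = 0.417), its mean (-0.0225) and median (-0.14) being negative where fry's direction was up. Of the 12 genes in the metal chelation list, 4 rose, 0 fell and 8 did not pass the test (4 and 0 when adjusted over the list alone), among them the vacuolar transporter gene ABCC2 (AT2G34660, 1.02 ± 0.20). On average the list moved by 0.32 (fry adjusted p = 0.0278; adjusted p = 0.411 with an estimated correlation), 0.0563 to 0.56 within slides and 0.32 with the slide as a block (adjusted p = 0.110). That call ended with any 1 of 3 arrays left out (0 h replicate 2, or 48 h replicate 2 or 3; adjusted p = 0.0678 to 0.0907), with median scaling (adjusted p = 0.127), with probe means (adjusted p = 0.0552) and with replicate as a block (adjusted p = 0.0673). It also ended with camera at the preset correlation (adjusted p = 0.0773) and without slides 3 and 4 (adjusted p = 0.168).

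Lists of tryptophan-derived and pathogen defence were called higher at 48 h. Of the 13 genes in the pathway of camalexin, the indole phytoalexin of this species, 9 rose, 1 fell and 3 did not pass the test (11 and 2 when adjusted over the list alone). CYP71A13 (AT2G30770, 3.96 ± 0.57) and the transcription factor gene NAC042 (AT2G43000, 4.17 ± 0.40) rose with CYP71A12. By fry, the mean shift of 1.94 had an adjusted p of 0.000547, against an adjusted p of 0.206 with an estimated correlation. Single slides gave 1.71 to 2.40, and the slide block gave 1.94 (adjusted p = 0.0186). Of 9 tryptophan synthesis genes, 6 rose, 0 fell and 3 did not pass the test (7 and 0 when adjusted over the list alone), the first enzyme's gene ASA1 (AT5G05730) by 1.70 ± 0.38 and TSB2 (AT4G27070) by 1.38 ± 0.16. These genes shifted by 0.93 on average (fry adjusted p = 0.00642, and an adjusted p of 0.411 with an estimated correlation). The shift was 0.85 to 1.06 within slides and 0.93 with a slide block (adjusted p = 0.0169). It ended without slides 3 and 4 (adjusted p = 0.0690). Among 12 indole glucosinolate genes, 3 rose, 0 fell and 9 did not pass the test (4 and 0 when adjusted over the list alone), namely CYP81F1 (AT4G37430, 1.81 ± 0.31), CYP81F2 (AT5G57220, 1.28 ± 0.30) and CYP81F4 (AT4G37410, 1.1 ± 0.22), whose enzymes modify the indole ring. As a set they moved by 0.56, with a fry adjusted p of 0.0119 and an adjusted p of 0.411 with an estimated correlation. Values within slides ran from 0.23 to 0.77, and the slide block gave 0.56 (adjusted p = 0.0700). Median scaling also ended it (adjusted p = 0.0767), as did leaving out slides 3 and 4 (adjusted p = 0.170). Salicylic acid and pathogenesis-related genes followed, where of 15 measured 10 rose, 1 fell and 4 did not pass the test (11 and 2 when adjusted over the list alone). The glucanase gene BGL2, also called PR2 (AT3G57260, 4.52 ± 0.61), and the salicylic acid synthesis gene PBS3 (AT5G13320, 3.62 ± 0.41) had the largest changes. Averaged over the list, the change was 1.75 (fry adjusted p = 0.000547; adjusted p = 0.206 with an estimated correlation). It was 1.41 to 2.03 on single slides and 1.75 with slide as a block (adjusted p = 0.0107). Of 14 jasmonate genes, 7 rose, 1 fell and 6 did not pass the test (7 and 2 when adjusted over the list alone), including VSP1 (AT5G24780, 3.49 ± 0.47) and VSP2 (AT5G24770, 3.38 ± 0.42). For the list, the mean change of 1.23 gave a fry adjusted p of 0.0472, and an adjusted p of 0.610 with an estimated correlation. On the separate slides the mean was 1.06 to 1.41, and with slide as a block 1.23 (adjusted p = 0.0136). The jasmonate call ended without any 1 of 7 arrays (0 h replicate 1, 2 or 3, 48 h replicate 2 or 3, or 72 h replicate 1 or 3; adjusted p = 0.0573 to 0.168), with median scaling (adjusted p = 0.0910) and without slides 3 and 4 (adjusted p = 0.259).

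Detoxification, heat shock and unfolded protein response lists were called higher at 48 h, the last with few of its genes called. Of 13 xenobiotic detoxification genes, 12 rose, 0 fell and 1 did not pass the test (12 and 0 when adjusted over the list alone), among them the alternative oxidase gene AOX1D (AT1G32350, 5.06 ± 0.47), CYP81D8 (AT4G37370, 4.14 ± 0.37) and the glutathione transferase gene GSTU25 (AT1G17180, 3.81 ± 0.34). The mean shift was 2.73 (fry adjusted p = 0.000216; adjusted p = 0.206 with an estimated correlation), between 2.63 and 2.87 within single slides, and with the slide as a block the shift was 2.73 (adjusted p = 0.000744). Heat shock genes, which encode chaperones, rose in 12 of 16 cases and fell in 0 (14 and 0 when adjusted over the list alone), as in HSP22.0 (AT4G10250, 3.89 ± 0.75, above background on 2 of 3 arrays at 0 h) and HSP17.6A (AT5G12030, 3.0 ± 0.51). Their mean shift of 2.02 had a fry adjusted p of 0.0119, and an adjusted p of 0.411 with an estimated correlation. Slide by slide it lay between 1.60 and 2.40, and with the slide as a block the shift was 2.02 (adjusted p = 0.0107). Without slides 3 and 4 it was not called (adjusted p = 0.112). Of 11 unfolded protein response genes, 2 rose, 0 fell and 9 did not pass the test (2 and 0 when adjusted over the list alone), with the endoplasmic reticulum chaperone gene BIP3 (AT1G09080) up by 3.97 ± 0.45 and SDF2 (AT2G25110) by 0.69 ± 0.13. On average the list moved by 0.67 (fry adjusted p = 0.0133; adjusted p = 0.411 with an estimated correlation), 0.48 to 1.01 within slides and 0.67 with the slide as a block (adjusted p = 0.0518). This call did not hold with the slide block, with median scaling (adjusted p = 0.0800) or without slides 3 and 4 (adjusted p = 0.0690).

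Lists of photosynthesis and of several tissues moved as well. Of 21 photosynthesis genes, 0 rose, 19 fell and 2 did not pass the test (0 and 21 when adjusted over the list alone), including the Calvin cycle gene PRK (AT1G32060, -1.91 ± 0.17), the Rubisco activase gene RCA (AT2G39730, -1.76 ± 0.19) and the antenna protein gene LHCA3 (AT1G61520, -1.41 ± 0.15). By fry, the mean shift of -1.17 had an adjusted p of 0.000431, against an adjusted p of 0.206 with an estimated correlation. Single slides gave -1.34 to -0.99, and the slide block gave -1.17 (adjusted p = 0.0107). Root and root hair markers divided into 1 that rose, 4 that fell and 8 not called, out of 13 (2 and 5 when adjusted over the list alone). COBL9, called SHV2 in the reference table (AT5G49270, -4.13 ± 0.46), a cell wall gene of root hairs, fell, and PRP1 (AT1G54970) was at least 9.92-fold lower. These genes shifted by -1.54 on average (fry adjusted p = 0.00195, and an adjusted p of 0.453 with an estimated correlation). The shift was -2.12 to -1.16 within slides and -1.54 with a slide block (adjusted p = 0.0263). It ended when probes had to be above background on all 9 arrays (mean -0.46, adjusted p = 0.401) and without slides 3 and 4 (adjusted p = 0.0589). Under the 4 other scalings the mean of the root list was -1.64 to -0.97. All 9 xylem and secondary wall markers rose (9 and 0 when adjusted over the list alone), for example the cellulose synthase genes IRX3 (AT5G17420, 1.00 ± 0.21) and IRX1 (AT4G18780, 0.97 ± 0.17) and their regulator MYB46 (AT5G12870, 1.03 ± 0.15). As a set they moved by 0.87, with a fry adjusted p of 0.000547 and an adjusted p of 0.206 with an estimated correlation. Values within slides ran from 0.79 to 0.97, and the slide block gave 0.87 (adjusted p = 0.0136). Of the 11 guard cell and epidermis markers, 0 rose, 3 fell and 8 did not pass the test (0 and 3 when adjusted over the list alone), one of them MUTE (AT3G06120, -1.43 ± 0.39), a stomatal lineage gene. Averaged over the list, the change was -0.68 (fry adjusted p = 0.0285; adjusted p = 0.411 with an estimated correlation). It was -1.22 to -0.0420 on single slides and -0.68 with slide as a block (adjusted p = 0.0693). Both this call and that of MUTE ended with single arrays left out: the list's without 0 h replicate 2 or 3, or 48 h replicate 1, 2 or 3 (adjusted p = 0.0510 to 0.135, with a mean of -0.43 without 0 h replicate 3), that of MUTE without 48 h replicate 1 or 3, or 0 h replicate 2 or 3 (adjusted p = 0.0573 to 0.0866). The list's call also ended in the deposited value table (mean -0.54, adjusted p = 0.0698) and without slides 3 and 4 (mean -0.40, adjusted p = 0.269).

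Ethylene response and phenylpropanoid lists were also called at 48 h. Silver blocks ethylene perception at the receptors. Of 16 ethylene response genes, 2 rose, 7 fell and 7 did not pass the test (3 and 8 when adjusted over the list alone), among them the receptor gene ERS2 (AT1G04310, -1.85 ± 0.16) and the F-box gene EBF2 (AT5G25350, -1.54 ± 0.15). For the list, the mean change of -0.50 gave a fry adjusted p of 0.00119, and an adjusted p of 0.322 with an estimated correlation. On the separate slides the mean was -0.62 to -0.29, and with slide as a block -0.50 (adjusted p = 0.0203). Of 17 phenylpropanoid and lignin genes, 8 rose, 2 fell and 7 did not pass the test (9 and 2 when adjusted over the list alone), with the ligase genes 4CL2 (AT3G21240, 1.45 ± 0.25) and 4CL1 (AT1G51680, 1.05 ± 0.21) higher. The mean shift was 0.39 (fry adjusted p = 0.0270; adjusted p = 0.453 with an estimated correlation), between 0.21 and 0.48 within single slides, and with the slide as a block the shift was 0.39 (adjusted p = 0.0855). The phenylpropanoid call ended without any 1 of 5 arrays (0 h replicate 1, 2 or 3, or 48 h replicate 2 or 3; adjusted p = 0.0618 to 0.0855). Replicate as a block (adjusted p = 0.0737), median scaling (adjusted p = 0.179) and leaving out slides 3 and 4 (adjusted p = 0.169) ended it too.

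The other lists were not called at 48 h without a block. They were flavonoid and anthocyanin genes (7 of 15 rose and 0 fell, 7 and 0 when adjusted over the list alone, mean 1.34, fry adjusted p = 0.149), ethylene synthesis genes (3 of 8 rose and 5 fell, 3 and 5 when adjusted over the list alone, mean -0.30, fry adjusted p = 0.0937), abscisic acid and dehydration genes (2 of 10 rose and 2 fell, 2 and 2 when adjusted over the list alone, mean 0.21, fry adjusted p = 0.904) and antioxidant enzyme genes (2 of 15 rose and 3 fell, 2 and 4 when adjusted over the list alone, mean -0.23, fry adjusted p = 0.326). Further ones were senescence and chlorophyll breakdown genes (3 of 12 rose and 1 fell, 3 and 2 when adjusted over the list alone, mean 0.35, fry adjusted p = 0.696), cell division genes (2 of 14 rose and 0 fell, 0 and 0 when adjusted over the list alone, mean 0.37, fry adjusted p = 0.204), aliphatic glucosinolate genes (0 of 15 rose and 0 fell, 0 and 0 when adjusted over the list alone, mean 0.55, fry adjusted p = 0.385), circadian clock genes (0 of 11 rose and 0 fell, 0 and 0 when adjusted over the list alone, mean -0.10, fry adjusted p = 0.438) and reference genes (0 of 10 rose and 1 fell, 0 and 1 when adjusted over the list alone, mean -0.10, fry adjusted p = 0.385). With replicate as a block, which here pairs arrays of the same slide, the ethylene synthesis list was called (adjusted p = 0.0435). With the slide itself as a block that list was not called (adjusted p = 0.0968). Without a block its adjusted p was 0.696 with an estimated correlation and 0.305 without slides 3 and 4. The aliphatic glucosinolate mean ran from -0.31 to 1.28 within slides, and was 0.0733 without 0 h replicate 3 and 0.92 without 0 h replicate 1. Means of the abscisic acid (-0.0404 to 0.47) and copper (-0.12 to 0.0882) lists changed sign with single arrays left out. Those of ethylene synthesis (-0.50 to -0.16, with a median of -1.32 in the full data), antioxidant (-0.31 to -0.14), senescence (0.16 to 0.46), clock (-0.21 to -0.00945) and reference genes (-0.15 to -0.0151) moved by over 1.5 times. In the flavonoid list the median was -0.0236 against the positive mean, and the anthocyanin genes PAP1 (AT1G56650, 4.93 ± 0.70) and DFR (AT5G42800, 4.06 ± 0.57) rose. ACS2 (AT1G01480, 3.17 ± 0.51) and ACS11 (AT4G08040, -1.91 ± 0.30), both for the enzyme that makes the ethylene precursor, went in opposite directions. For abscisic acid genes fry's direction was down while mean and median (0.35) were positive, and for reference genes the median was 0.0400 while the mean and fry's direction were negative. ACT2 (AT3G18780), an actin gene, fell (-0.83 ± 0.19), a call lost with quantile normalization (adjusted p = 0.0866), and the other 9 lay between -0.53 and 0.37. The lowest of these, ACT8 (AT1G49240), was called with replicate as a block (adjusted p = 0.0202). So was the aliphatic glucosinolate gene SOT17 (1.03, adjusted p = 0.0416).

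Gene families, grouped by the letters that open their symbols, were tested among genes called higher or lower at 48 h, out of 9232 genes with a symbol. Fisher's exact test treats genes of a family as independent, here and at 72 h. Its p therefore does not measure the spread between experiments. NAC transcription factor genes had the smallest p among rises (36 of 67, adjusted p = 1.13e-10), followed by GSTU glutathione transferases (16 of 27, adjusted p = 1.34e-05), WRKY factors (26 of 62) and UGT glycosyltransferases (24 of 55). SAUR (10 of 14), MYB (31 of 93), CRK (16 of 38), ABCC (9 of 15), BGLU (13 of 30), IRX (8 of 10) and CYP (47 of 187) families were also over-represented among rises, with adjusted p up to 0.00649. Among falls were EMB genes, named for embryo-lethal mutants (58 of 156, adjusted p = 2.96e-08), the plastid families HCF (11 of 12), PTAC (12 of 14) and CRR (9 of 11), and XTH cell wall genes (12 of 27, adjusted p = 0.00907). RLP, HSP and OFP among rises and PDE and ERF among falls passed here but not under every other scaling, where their highest adjusted p was 0.515, 0.439, 1.00, 0.0504 and 0.0880.

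**Figure D1:**
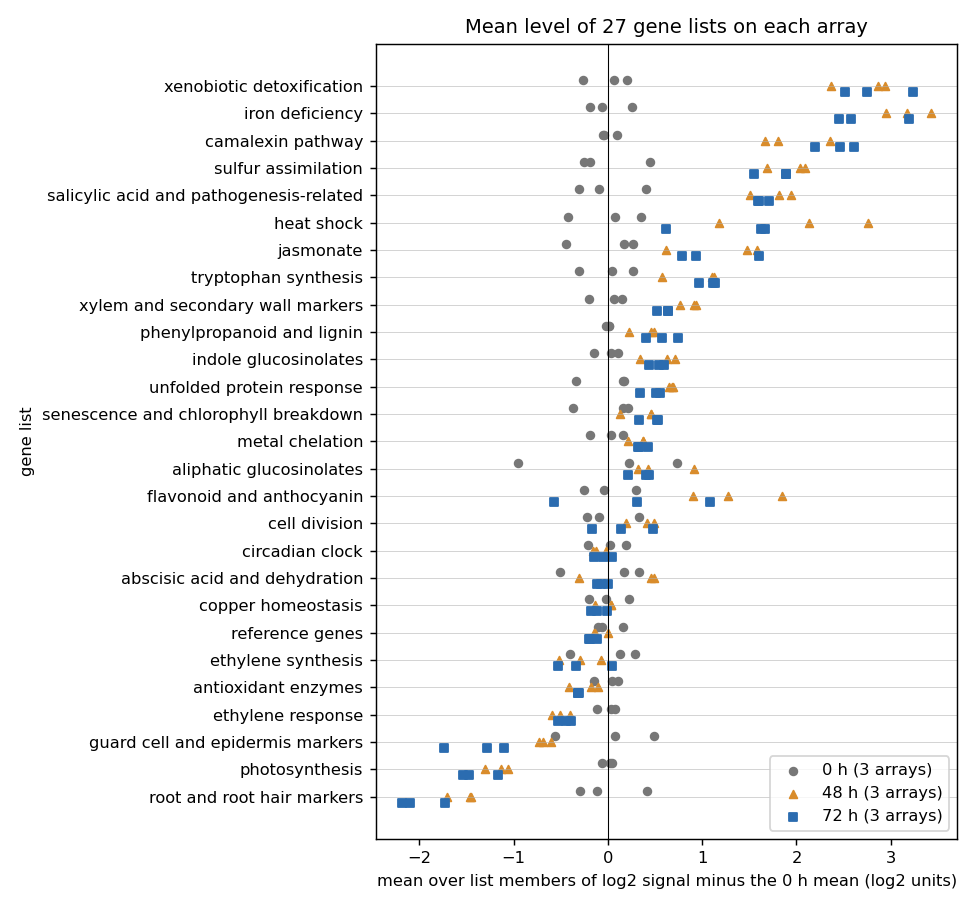
Mean log2 signal of each of the 27 gene lists on each array, relative to the mean of the 3 arrays at 0 h (horizontal axis, log2 units); circles, triangles and squares are the arrays of 0 h, of 48 h and of 72 h. Detoxification, iron deficiency and camalexin genes lie highest at 72 h (means 2.84, 2.74 and 2.42), and root markers lowest (-2.00).

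After 72 h, genes of iron regulation and indole defence were again among the largest rises. The carboxypeptidase-like gene scpl30 rose 208-fold (7.70 ± 0.68, adjusted p = 0.000103), bHLH38 159.5-fold (7.32 ± 0.50) and CYP82C2 137-fold (7.10 ± 0.71). CYP71A12 (6.6 ± 0.43), bHLH39 (6.30 ± 0.41) and DIN2 (6.43 ± 0.77) followed, with the ubiquitin ligase gene PUB54 (AT1G01680, 5.70 ± 0.38) and the methyltransferase gene PXMT1 (AT1G66700, 5.65 ± 0.38). NEET fell 102-fold (-6.67 ± 0.42) and RRTF1 102-fold (-6.68 ± 0.63), and CBF4 (-6.07 ± 0.40), FBA5 (-5.64 ± 0.62), XTH14 (-5.55 ± 0.52) and CA1 (-5.46 ± 0.37) were lower too. TIP2;3 (AT5G47450, -5.87 ± 0.53), which encodes a vacuolar water channel, and the root hair gene COBL9 (-5.71 ± 0.46) were also among the largest falls.

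Lower bounds at 72 h were 78.2-fold for the rise of SUC7, 48.6-fold for ACA7 (AT1G08080), a carbonic anhydrase gene, 19.7-fold for ARI12 (AT1G05880), a ubiquitin ligase gene, and 19.3-fold for HVA22J (AT2G36020). RHS18 was at least 47.6-fold lower, RALFL27 (AT3G29780), a signalling peptide gene, at least 35.7-fold lower, MLO15 (AT2G44110) at least 33.1-fold lower and CYP718 at least 31.7-fold lower. In all, 7628 of 21042 genes (36.3%) were called, 3505 higher and 4123 lower, of which 1921 rose and 2496 fell at least 2-fold. Of all calls 45.9% were higher, against 37.3% with normexp, 45.4% with median scaling, 50.2% with quantile normalization and 65.2% in the deposited value table, where the median of all genes moved by 0.231. Without slides 3 and 4, 4418 genes passed. Of genes named here for 72 h, the calls of GSH2, PRP3, SPCH, IRX3, MYB46, 4CL3, DFR and LDOX then ended (adjusted p = 0.0546 to 0.0846).

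At 72 h, of 11 iron deficiency genes, 7 rose, 2 fell and 2 did not pass the test (7 and 2 when adjusted over the list alone), with BHLH100 at 8.45 ± 0.88 (above background on 2 of 3 arrays at 0 h). Their mean shift of 2.74 had a fry adjusted p of 0.000147, and an adjusted p of 0.265 with an estimated correlation. Slide by slide it lay between 2.33 and 2.64, and with the slide as a block the shift was 2.44 (adjusted p = 0.00110). Beside FER1 (-3.11 ± 0.36), FIT1 fell (-1.47 ± 0.43), a gene for the regulator of iron uptake in roots that was named after its values were seen. This fall was not called without 72 h replicate 2 or 3 (adjusted p = 0.0543 and 0.0932). Of 14 sulfur assimilation genes, 11 rose, 1 fell and 2 did not pass the test (11 and 1 when adjusted over the list alone). GGCT2;1 (4.64 ± 0.47) and BGLU28 (4.55 ± 0.84) rose and SULTR1;1 was at least 4.63-fold lower. On average the list moved by 1.78 (fry adjusted p = 0.000938; adjusted p = 0.302 with an estimated correlation), 1.45 to 1.74 within slides and 1.70 with the slide as a block (adjusted p = 0.0149). Of 14 copper genes, 5 rose, 5 fell and 4 did not pass the test (5 and 7 when adjusted over the list alone; fry adjusted p = 0.634), with ZIP2 (-3.62 ± 0.29) and FSD1 (-3.0 ± 0.32) lower and ARPN (2.53 ± 0.31) higher. The copper list's mean (-0.10) and median (-0.15) were negative and fry's direction was up. Metal chelation genes gave 4 rises and 0 falls among 12 (4 and 0 when adjusted over the list alone), including ABCC2 (1.07 ± 0.20) and the glutathione synthetase gene GSH2 (AT5G27380, 0.90 ± 0.21). By fry, the mean shift of 0.36 had an adjusted p of 0.0246, against an adjusted p of 0.483 with an estimated correlation. Single slides gave 0.26 to 0.30, and the slide block gave 0.34 (adjusted p = 0.164). This call ended without 0 h replicate 2, or 72 h replicate 1 (adjusted p = 0.0533 and 0.0813), with probe means (adjusted p = 0.0504) and with replicate as a block (adjusted p = 0.0775). Camera at the preset correlation (adjusted p = 0.113), list loci looked up by symbol (adjusted p = 0.0534) and leaving out slides 3 and 4 (adjusted p = 0.0877) ended it as well.

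**Figure D2:**
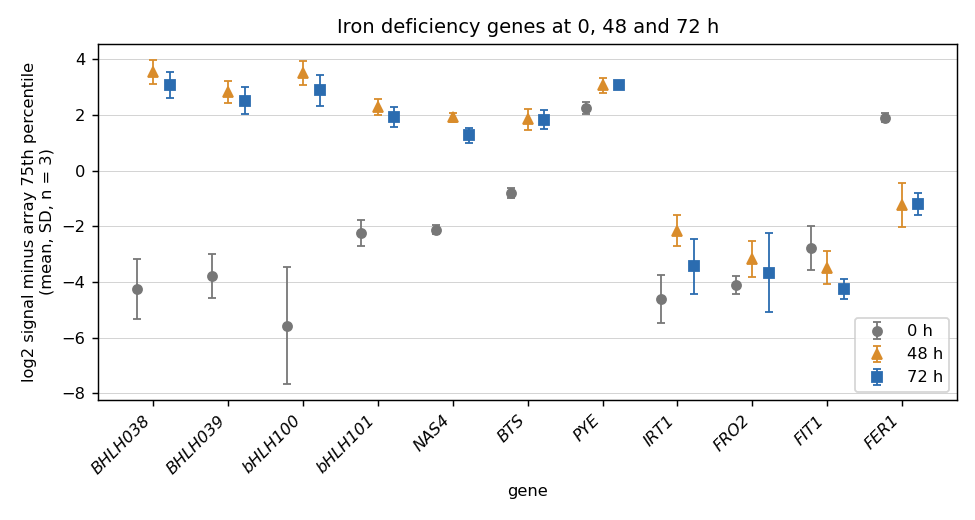
Mean log2 signal relative to the 75th percentile of each array (vertical axis, log2 units) of 11 measured iron deficiency genes at the 3 times; points are means and bars are SD of 3 arrays. bHLH38, bHLH39, bHLH100 and bHLH101 lie far above their 0 h means at both later times, and FER1 lies below (changes of -3.14 and -3.11).

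**Figure D3:**
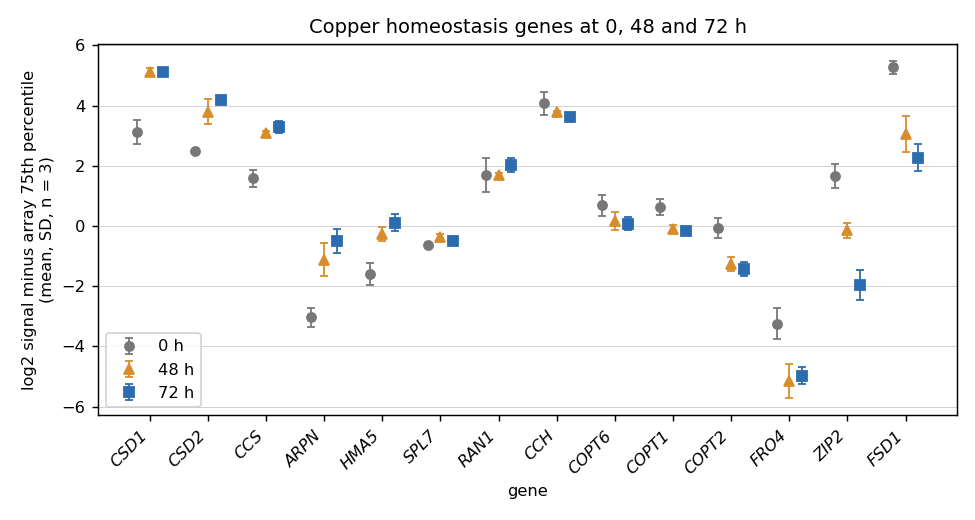
Mean log2 signal relative to the 75th percentile of each array (vertical axis, log2 units) of 14 measured copper homeostasis genes at the 3 times; points are means and bars are SD of 3 arrays. The 5 genes at the left were called higher at both later times, the 5 at the right lower and the 4 between them neither, from ARPN (2.53 at 72 h) to ZIP2 (-3.62 at 72 h).

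Most defence lists were called higher at 72 h too. Of 13 camalexin pathway genes, 10 rose, 0 fell and 3 did not pass the test (10 and 0 when adjusted over the list alone), CYP71A13 by 5.49 ± 0.57 and NAC042 by 5.38 ± 0.40. These genes shifted by 2.42 on average (fry adjusted p = 0.000223, and an adjusted p of 0.265 with an estimated correlation). The shift was 2.1 to 2.67 within slides and 2.50 with a slide block (adjusted p = 0.0164). Of 9 tryptophan synthesis genes, 7 rose, 0 fell and 2 did not pass the test (7 and 0 when adjusted over the list alone), with ASA1 at 1.88 ± 0.38 and TSB2 at 1.70 ± 0.16. As a set they moved by 1.07, with a fry adjusted p of 0.00251 and an adjusted p of 0.414 with an estimated correlation. Values within slides ran from 1.08 to 1.44, and the slide block gave 1.24 (adjusted p = 0.0164). Indole glucosinolate genes gave 3 rises and 0 falls of 12 (3 and 0 when adjusted over the list alone), led by CYP81F1 (1.99 ± 0.31) and CYP81F2 (1.83 ± 0.30). Averaged over the list, the change was 0.53 (fry adjusted p = 0.0287; adjusted p = 0.483 with an estimated correlation). It was 0.49 to 0.51 on single slides and 0.55 with slide as a block (adjusted p = 0.164). That list was no longer called without 0 h replicate 2 or 3, or 72 h replicate 1 or 2 (adjusted p = 0.0596 to 0.0830), with median scaling (adjusted p = 0.0611) or without slides 3 and 4 (adjusted p = 0.169). Of 15 salicylic acid and pathogenesis-related genes, 10 rose, 1 fell and 4 did not pass the test (11 and 1 when adjusted over the list alone), BGL2 by 4.13 ± 0.61 and FMO1 (AT1G19250), a gene of systemic resistance, by 3.30 ± 0.49. For the list, the mean change of 1.64 gave a fry adjusted p of 0.000938, and an adjusted p of 0.265 with an estimated correlation. On the separate slides the mean was 1.21 to 1.90, and with slide as a block 1.63 (adjusted p = 0.0164). The jasmonate list was not called without a block (mean 1.11, fry adjusted p = 0.0782), but was called with the slide (1.32, adjusted p = 0.0164) or replicate (adjusted p = 0.0374) as a block. Unblocked, it was not called with an estimated correlation (adjusted p = 0.718) or without slides 3 and 4 (adjusted p = 0.251). Of 14 genes, 5 rose, 2 fell and 7 did not pass the test (7 and 2 when adjusted over the list alone), with VSP1 (3.77 ± 0.47) and VSP2 (3.49 ± 0.42) higher.

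Of 13 detoxification genes, 12 rose, 0 fell and 1 did not pass the test at 72 h (12 and 1 when adjusted over the list alone), with AOX1D at 5.45 ± 0.47 and CYP81D8 at 4.25 ± 0.37. The mean shift was 2.84 (fry adjusted p = 0.000147; adjusted p = 0.265 with an estimated correlation), between 2.56 and 2.78 within single slides, and with the slide as a block the shift was 2.70 (adjusted p = 0.00130). Heat shock genes (6 of 16 rose and 0 fell, 6 and 0 when adjusted over the list alone, mean 1.3, fry adjusted p = 0.0514) and unfolded protein response genes (2 of 11 rose and 0 fell, 2 and 0 when adjusted over the list alone, mean 0.47, fry adjusted p = 0.0514) were not called as lists without a block, although BIP3 rose (3.30 ± 0.45). The heat shock list was called with the slide (1.41, adjusted p = 0.0174) or replicate (adjusted p = 0.00724) as a block, while the unfolded protein response list, whose mean was 0.30 without 0 h replicate 1, was not (adjusted p = 0.120 and 0.0914). Unblocked, heat shock was not called with an estimated correlation (adjusted p = 0.532) or without slides 3 and 4 (adjusted p = 0.168). Its mean was 0.81 to 1.53 under the 4 other scalings (fry adjusted p up to 0.158). Photosynthesis genes fell in 20 of 21 cases and rose in 0 (0 and 21 when adjusted over the list alone), as in PRK (-2.02 ± 0.17) and LHCA3 (-1.72 ± 0.15). Their mean shift of -1.39 had a fry adjusted p of 0.000147, and an adjusted p of 0.265 with an estimated correlation. Slide by slide it lay between -1.41 and -1.20, and with the slide as a block the shift was -1.3 (adjusted p = 0.0149).

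Of 13 root and root hair markers, 3 rose, 6 fell and 4 did not pass the test at 72 h (3 and 8 when adjusted over the list alone), where PRP1 and PRP3 (AT3G62680), for wall proteins of root hairs, were at least 13.5-fold and at least 12.6-fold lower. On average the list moved by -2.00 (fry adjusted p = 0.000938; adjusted p = 0.483 with an estimated correlation), -2.60 to -1.43 within slides and -1.97 with the slide as a block (adjusted p = 0.0292). The call ended when probes had to be above background on all 9 arrays (mean -0.67, adjusted p = 0.218) and with camera at the preset correlation (adjusted p = 0.0522). Guard cell and epidermis markers fell in 8 of 11 cases and rose in 0 (0 and 8 when adjusted over the list alone), among them the stomatal lineage genes SPCH (AT5G53210, -3.33 ± 0.76, above background on 2 of 3 arrays at 72 h) and MUTE (-2.24 ± 0.39). By fry, the mean shift of -1.38 had an adjusted p of 0.00173, against an adjusted p of 0.302 with an estimated correlation. Single slides gave -1.36 to -1.17, and the slide block gave -1.40 (adjusted p = 0.0174). Xylem and secondary wall markers rose in 7 of 9 cases and fell in 0 (8 and 0 when adjusted over the list alone), including IRX3 (0.84 ± 0.21) and MYB46 (0.77 ± 0.15). These genes shifted by 0.59 on average (fry adjusted p = 0.00251, and an adjusted p of 0.342 with an estimated correlation). The shift was 0.37 to 0.84 within slides and 0.60 with a slide block (adjusted p = 0.0345). It was not called without slides 3 and 4 (adjusted p = 0.0602).

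Among 16 ethylene response genes, 2 rose, 7 fell and 7 did not pass the test at 72 h (2 and 7 when adjusted over the list alone), with ERS2 at -1.81 ± 0.16 and EBF2 at -1.67 ± 0.15. As a set they moved by -0.45, with a fry adjusted p of 0.00251 and an adjusted p of 0.433 with an estimated correlation. Values within slides ran from -0.56 to -0.52, and the slide block gave -0.49 (adjusted p = 0.0388). The ethylene response call ended in the deposited value table (mean -0.22, adjusted p = 0.109) and with camera at the preset correlation (adjusted p = 0.135). Of 17 phenylpropanoid and lignin genes, 9 rose, 3 fell and 5 did not pass the test (11 and 3 when adjusted over the list alone), 4CL2 rising by 1.86 ± 0.25 and 4CL3 (AT1G65060) changing by -1.39 ± 0.25. Averaged over the list, the change was 0.58 (fry adjusted p = 0.00443; adjusted p = 0.433 with an estimated correlation). It was 0.56 to 0.74 on single slides and 0.67 with slide as a block (adjusted p = 0.0292). Flavonoid and anthocyanin genes divided, since of 15 genes 5 rose, 7 fell and 3 did not pass the test (6 and 7 when adjusted over the list alone), with PAP1 (3.44 ± 0.70) and DFR (2.59 ± 0.57) higher. That list was not called (fry adjusted p = 0.948), its mean (0.28) and median (0.16) being positive where fry's direction was down. Its mean was -0.13 without 72 h replicate 2 and 0.70 without 72 h replicate 1, and ran from -0.32 to 1.13 within slides.

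Further lists not called at 72 h without a block were ethylene synthesis genes (3 of 8 rose and 4 fell, 3 and 4 when adjusted over the list alone, mean -0.28, fry adjusted p = 0.0858), abscisic acid and dehydration genes (1 of 10 rose and 2 fell, 1 and 2 when adjusted over the list alone, mean -0.0613, fry adjusted p = 0.0687) and antioxidant enzyme genes (2 of 15 rose and 5 fell, 2 and 5 when adjusted over the list alone, mean -0.32, fry adjusted p = 0.222). Senescence, cell division and clock lists were not called either: senescence and chlorophyll breakdown genes (3 of 12 rose and 1 fell, 3 and 1 when adjusted over the list alone, mean 0.46, fry adjusted p = 0.197), cell division genes (1 of 14 rose and 0 fell, 0 and 0 when adjusted over the list alone, mean 0.15, fry adjusted p = 0.579) and circadian clock genes (0 of 11 rose and 0 fell, 0 and 0 when adjusted over the list alone, mean -0.0521, fry adjusted p = 0.748). The same held for aliphatic glucosinolate genes (0 of 15 rose and 0 fell, 0 and 0 when adjusted over the list alone, mean 0.35, fry adjusted p = 0.635) and reference genes (0 of 10 rose and 1 fell, 0 and 1 when adjusted over the list alone, mean -0.17, fry adjusted p = 0.0878). The abscisic acid list was called with the slide (-0.29, adjusted p = 0.0149) or replicate (adjusted p = 0.0202) as a block. The ethylene synthesis list was called with replicate as a block (adjusted p = 0.0494) but not with the slide (-0.31, adjusted p = 0.164). Unblocked, with an estimated correlation, these 2 lists had an adjusted p of 0.736 and 0.736, and without slides 3 and 4 of 0.0293 and 0.396. Of the 72 h arrays, only replicate 1 had deviations that correlated best with the 0 h array of its own number. The aliphatic glucosinolate mean ran from -0.33 to 0.20 within slides and was -0.13 without 0 h replicate 3. With single arrays left out the means of abscisic acid (-0.31 to 0.11), copper (-0.20 to 0.00948), cell division (-0.0161 to 0.31) and clock genes (-0.16 to 0.0422) also changed sign. Means of ethylene synthesis (-0.48 to -0.13, with a median of -1.1 in the full data), senescence (0.27 to 0.56) and reference genes (-0.22 to -0.0906) moved by over 1.5 times. Single members of these lists changed, such as ACS2 (3.92 ± 0.51), the dehydrin gene ERD10 (AT1G20450, -1.62 ± 0.13), the catalase gene CAT2 (AT4G35090, -1.64 ± 0.33), the senescence gene SAG13 (AT2G29350, 4.11 ± 0.45) and the chlorophyll b reductase gene NYC1 (AT4G13250, -2.32 ± 0.25). The aliphatic glucosinolate gene with the smallest p was SOT17 (AT1G18590, 0.79 ± 0.37, adjusted p = 0.135), and the clock gene with the smallest p was PRR5 (AT5G24470, 0.52 ± 0.22, adjusted p = 0.106). With replicate as a block PRR5 and the actin gene ACT8 (-0.41) were called (adjusted p = 0.0408 and 0.0409).

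Over-represented families among rises at 72 h were NAC (36 of 67, adjusted p = 4.13e-09), MYB (41 of 93, adjusted p = 2.35e-07), WRKY (30 of 62), BGLU (17 of 30), ABCC (11 of 15), GSTU (15 of 27), UGT (23 of 55), CRK (17 of 38) and ABCG transporters (15 of 38), with adjusted p up to 0.0158. Falls were enriched in PTAC (13 of 14), arabinogalactan proteins of the AGP family (19 of 27, adjusted p = 3.16e-06), EMB (59 of 156), HCF (10 of 12), XTH (16 of 27), CRR (9 of 11) and KCS genes of very long chain fatty acid synthesis (11 of 17, adjusted p = 0.00245). RLP, CYP, IRX, SULTR and LBD among rises and PDE and PIP among falls passed here but not under every other scaling (highest adjusted p = 0.512, 0.699, 0.329, 0.303, 0.583, 0.0878 and 1.00).

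Between 72 h and 48 h no gene passed the limma test, and 1941 genes had an unadjusted p under 0.05 (710 higher and 1231 lower at 72 h). The smallest adjusted p was 0.0517, for AT5G56075 (2.12 ± 0.19). AT1G14960 (-4.54, adjusted p = 0.0582) and the expansin gene EXPA2 (-2.46, adjusted p = 0.0941) came next. These genes were named after their values were seen. No list was called between the later times by fry, while camera with a preset correlation called 8 (2 higher and 6 lower at 72 h) and camera with an estimated correlation called 0. With single arrays left out, 7 genes passed without 48 h replicate 3, 5 without 72 h replicate 2, 2 without 72 h replicate 1, and 1 each without 0 h replicate 2, 0 h replicate 3 or 72 h replicate 3.

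Genes called at 48 h and 72 h were set side by side. In all, 5556 genes were called in the same direction at both times, 2496 higher and 3060 lower, against 494.4 and 652.5 if the calls were independent. Both comparisons use the same 3 arrays at 0 h, which cannot be divided between them, so the excess includes whatever the shared reference adds. In 50 simulated data sets with no change but a shared reference, 0 genes were called at both times in the same direction. With no change simulated, hardly any gene can be called at either time. This count therefore does not show how much of the overlap the shared reference adds. Across genes the changes correlated at 0.927, and the simulations gave 0.502. The covariance was 1.07 in the data and 0.0474 in the simulations, a difference of 1.02. Of the 48 h calls, 99.4% had the same sign at 72 h. The shared arrays at 0 h raise this share as well, and no simulated value was made for it. Only 2 genes were called in opposite directions, and they are named because of that: AT3G59340 (0.59 at 48 h and -0.46 at 72 h) and the triterpene gene CYP708A2 (AT5G48000, 0.88 and -0.72). Their direct difference between 72 h and 48 h was not called (adjusted p = 0.123 for each). An F test over the 3 times called 6900 genes.

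**Figure D4:**
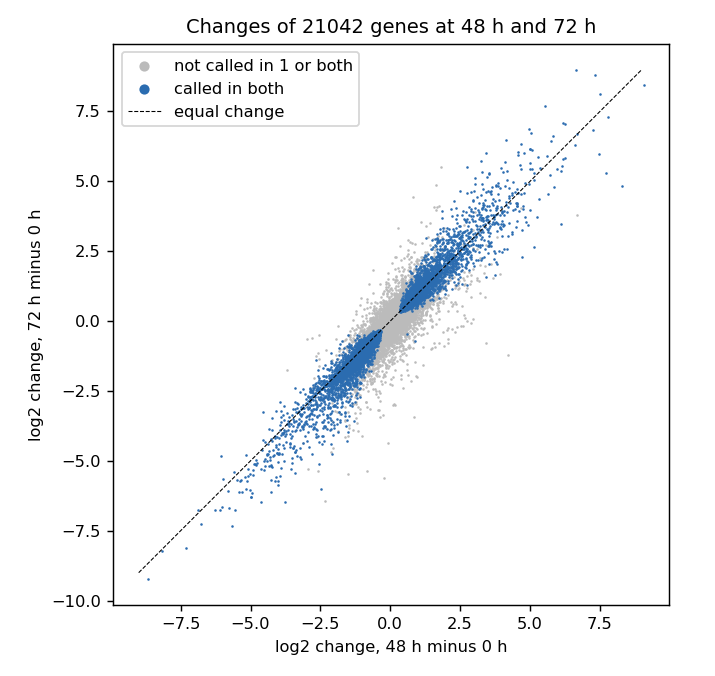
log2 change of each of the 21042 genes tested, 48 h minus 0 h (horizontal axis) against 72 h minus 0 h (vertical axis), with genes called in both comparisons in blue and the line of equal change dashed. The changes share the 3 arrays at 0 h and correlate across genes at 0.927.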

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

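The tests of the root pattern with raised signals, with dim genes left out and of scaling, the touch list without CBF genes, and the single-array test and repeated counts of the iron pattern were chosen after the result was seen. Probes without a locus took no part in the comparisons of genes, yet some changed. Of probes designed on genome positions, 144 were called higher and 260 lower at 48 h than at 0 h, and 159 higher and 342 lower at 72 h, among 2012 tested. Of probes designed on expressed sequence tags or other accessions, 50 were called higher and 104 lower at 48 h, and 74 higher and 159 lower at 72 h, among 1213 tested.

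A list of 25 genes that respond within minutes to touch and wounding, CBF2 among them, written after the falls of CBF2 and RRTF1 were seen, was lower at both later times. At 48 h 20 fell and 0 rose (mean -1.76, fry p = 3.98e-05; p = 0.0435 with an estimated correlation; -1.97 to -1.59 within slides and -1.76 with a slide block), and at 72 h 18 fell (mean -1.79, p = 4.45e-05; p = 0.0667 with an estimated correlation; -1.85 to -1.69 within slides and -1.76 with a slide block); without CBF2 the means were -1.65 (fry p = 5.65e-05; p = 0.0448 with an estimated correlation) and -1.64 (p = 7.18e-05 and 0.0698), and without CBF1, CBF2 and CBF3 they were -1.60 (p = 9.47e-05 and 0.0615) and -1.57 (p = 0.000128 and 0.0937). A single array at 0 h is argued against, since 3 of 3 arrays at 0 h lay above all later arrays, and so is scaling, since the shift at 72 h closest to 0 under 4 other scalings was -1.56 (-1.42 without CBF2). Handling of the 0 h plants shortly before harvest is a candidate explanation that stays open, because every 0 h sample would share it. An effect of silver or of time in culture stays open for the same reason and was not tested.

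The root and root hair list was called lower at 72 h by fry (mean -2.00, 6 of 13 lower and 3 higher), but not with probes above background on all 9 arrays (-0.67, adjusted p = 0.218) or by camera with a preset (adjusted p = 0.0522) or estimated (adjusted p = 0.483) correlation. A lower share of root tissue would lower hair genes and other root genes alike, if all of them measured that share. With signals raised to the lowest value above background on each array, 7 hair genes changed by -3.09 on average. The 6 other root genes, above background on every array, changed by -0.00691 (-1.19 to 1.41). The difference was -3.09 (exact permutation test over genes, two-sided p = 0.0122, 1716 arrangements). That test treats genes as independent. The other root genes did not move together: CASP1 (-1.19) was called lower, PLT2 (1.41) and SHR (0.63) higher. Their mean covers opposite changes, so it does not measure the share of root. An equal fall of hair genes and other root genes is argued against. A lower root share stays open, as part or the whole of the cause. Leaving out the 4 hair genes that were not above background on all arrays at 72 h (-2.00, exact permutation test, p = 0.202) selects on the fall itself and was not used. Scaling is argued against by a shift of -1.20, the value closest to 0 among 4 other scalings. A change of root hairs or of their genes is a candidate explanation, a hypothesis found on the same data, and loss of hairs in culture without silver stays open, since no untreated plants of 48 h or 72 h were analysed here.

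The iron deficiency list was called higher by fry at both later times (8 of 11 genes higher and 1 lower at 48 h, 7 and 2 at 72 h), but not with an estimated correlation (adjusted p = 0.206 and 0.265). A single array is argued against, since 6 of 6 later arrays had a list mean above all arrays at 0 h. An iron-deficiency-like response of the whole list should raise at least 5 of IRT1, FRO2, FIT1, PYE, BTS, NAS4 and CYP82C4 at 72 h and lower FER1. Of the 6 measured, 3 were called higher (PYE, BTS and NAS4, with 3 to 4 under 4 other scalings or with single arrays left out). FER1 was called lower. The list thus did not respond alike at 72 h. This does not exclude such a response, since IRT1, FRO2 and FIT1 act in the root, where 5 of 7 hair genes fell, and 48 h was not counted. FIT1 was called lower (not without 72 h replicate 2 or 3), CYP82C4 was not measured, and IRT1 was called higher at 48 h (2.47 ± 0.57) but not at 72 h. A response of part of the list may remain, and whether a change of root hairs, silver or the state of the culture is the source of the difference between members was not tested.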

How the results depend on the processing

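Leaving out slides 3 and 4 together was chosen after the data were seen. The lookup of list loci by symbol, planned as the rule and replaced before expression values were seen, was added as an alternative; every other setting was planned. The 194 called results of named genes were recomputed under 20 settings: 148 calls were never lost and 0 calls reversed. Of 6540 values for all 330 gene results, 6391 kept their side of the threshold, 122 were weaker and 27 stronger. Values that were not called could change sign and still count as kept, for genes and for lists. For lists, 0 of 31 calls held under all of 23 settings, because camera with an estimated correlation called 0 lists at 48 h and 0 at 72 h. Of 1863 list values, 1721 kept their side of the threshold, 96 were weaker and 46 stronger, and 0 calls reversed. The slide block kept 12 of 17 calls at 48 h and 12 of 14 at 72 h, the replicate block 15 and 13, and all 4 other scalings 11 and 12. In 72 h against 48 h, where 0 genes passed, 1 passed with normexp, 3 with quantile normalization, 2 with median scaling, 1 in the deposited value table, 6 with replicate as a block, 6 with slide as a random block, 3 with only the 6 arrays compared and 1 with an intensity trend; camera with a preset correlation called 8 lists there. The cause was not tested. Correlations of deviations between same-numbered arrays were 0.209, -0.00955 and 0.116 for 72 h and 0 h. For 72 h and 48 h they were 0.0979, 0.112 and -0.0391. The 72 h array matched its own number best for replicate 1 against 0 h, and for replicates 1 and 2 against 48 h. Replicate 3 of 72 h shared its number but no slide with other arrays, and matched its own number best in neither comparison. As 1 array, it does not decide between pairing by number and by slide. Requiring 2-fold left 3594 genes at 48 h and 4417 at 72 h, by construction. Without slides 3 and 4, with 6 arrays, 3024 genes passed at 48 h, 4418 at 72 h, 3273 in the F test and 2706 at both times, with 8 lists and 13 families at 48 h. With each array left out in turn, calls ranged from 4654 to 6972 genes at 48 h, 5640 to 8437 at 72 h, 0 to 7 for 72 h against 48 h, 4945 to 7395 in the F test and 4179 to 6214 at both times; lists from 13 to 18 at 48 h, 12 to 16 at 72 h and 0 to 0 between them; families from 16 to 26 and 19 to 23. Signal over background limits calls to lower bounds where it is lacking at 0 h (126 calls at 48 h and 145 at 72 h) or at the later time (137 and 168).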

Other observations

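No test in this part was chosen after its result was seen, but the hypotheses were formed after the list results. Copper genes moved in opposite directions. The copper/zinc superoxide dismutase genes CSD1 (2.01 ± 0.20 at 48 h and 1.99 ± 0.20 at 72 h) and CSD2 (1.32 ± 0.19 and 1.72 ± 0.19), their copper chaperone gene CCS (1.49 ± 0.17 and 1.71 ± 0.17) and the copper pump gene HMA5 (1.33 ± 0.23 and 1.71 ± 0.23) rose, genes named after their values were seen. The uptake genes COPT2 (-1.19 ± 0.21 and -1.35 ± 0.21) and FRO4 (-1.91 ± 0.34 and -1.73 ± 0.34) fell, as did FSD1 and ZIP2 above. A fall of the copper-responsive microRNAs, which repress CSD1, CSD2, CCS and laccase genes when copper is scarce, is a hypothesis for the rises of CSD1, CSD2 and CCS. It does not cover the rise of HMA5 or the falls, whose cause was not tested. Of 5 further targets chosen from outside the copper list, LAC2, LAC3, LAC12, LAC13 and COX5B-1, 2 were called higher at 72 h: LAC12 (2.73) and LAC13 (0.75). These 5 moved by 0.84 on average (fry p = 0.00167, and p = 0.126 with an estimated correlation). The test does not decide, since 5 genes are few and the microRNAs themselves were not measured.

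Members of the flavonoid list went both ways at 72 h. TT4 (-1.95 ± 0.59), TT5 (-0.85 ± 0.24), F3H (-1.36 ± 0.46), TT7 (-1.61 ± 0.42), FLS1 (-2.28 ± 0.51), UGT78D2 (-0.70 ± 0.18) and the regulator gene MYB111 (-1.97 ± 0.46) fell. DFR (2.59 ± 0.57), LDOX (2.43 ± 0.64), UGT75C1 (1.3 ± 0.35), GSTF12 (2.03 ± 0.58) and the regulator gene PAP1 rose. UGT79B1, TT8 and MYB12 were not called, and early and late genes were not tested against each other. The call of LDOX ended with normexp, without 0 h replicate 2, 72 h replicate 2 or 72 h replicate 3, and without slides 3 and 4 (adjusted p = 0.0517 to 0.0826), and that of DFR without slides 3 and 4 (adjusted p = 0.0779). At 48 h none of TT4, F3H and FLS1 was called (-0.22, -0.53 and -1.14), and the difference between the times was not called for any gene. These genes were named after their values were seen.

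Sulfur and iron genes could rise because the culture ran out of nutrients in general. Then lists of phosphate starvation, nitrate-induced and sugar starvation genes would move as in starvation, and 0 of these 3 did at 72 h (means -0.00588, 0.0565 and -0.10, adjusted p = 0.989 for each). At 48 h their adjusted p was 0.124, 0.582 and 0.111, the last for a fall of sugar starvation genes. These lists do not decide: at 72 h 3 phosphate starvation genes rose and 5 fell, 1 nitrate-induced gene rose and 2 fell, and 0 of 10 sugar starvation genes rose and 1 fell, and a p above the threshold does not show that a list did not move. General run-down of nutrients stays open, and a lack of sulfur or iron alone was not tested.

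Other splits of the arrays were counted. For 48 h against 0 h the real split of the 6 arrays called 5118 genes and the highest of the other splits 0; for 72 h against 0 h these were 6642 and 0, and for 72 h against 48 h 3 and 0. In each case 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. For 48 h against 0 h, where same-numbered arrays share a slide, 4 splits part all 3 pairs as the real one does, and the highest other among them called 0. For the F test, 1 of 100 splits drawn from 280, the real one, gave as many as the real 6900, a share under 0.05. These splits were drawn without regard to slide or replicate number. The highest other split called 6171. That split was 1 of 6 others that kept the 3 arrays at 0 h together (5673 to 6171 genes), while the 93 that mixed 0 h with later arrays called at most 1 gene. Such splits point to a structure of the samples, 0 h against both later times.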
